A study of Halobacterium salinarum NRC-1 with 16 samples.

How the data were processed

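RNA of 8 mutant samples, at 4 MnSO4 doses with 2 sets (A and B) each, was measured on 16 two-colour arrays. Each sample was hybridised on 2 arrays with the dyes Alexa 532 and Alexa 647 exchanged, against RNA of an NRC-1 control, per the labels. The deposited table holds 1 value per spot and array: a log ratio of the 2 dye channels made by the authors, whose base, background correction and normalization are not given in the sources used here. No spot intensity, quality mark or background was used here, so brightness is unknown. The protocols in the labels describe a total RNA preparation free of DNA. On the 8 arrays with the mutant in Alexa 647, the growth text names 6.0 mM FeSO4 for 80 minutes for the mutant culture, while titles and sources name manganese, and the titles and sources were followed.

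Spots were grouped into features from the layout of the values. Neighbouring spots correlated with r = 0.926 and spots 5376 places apart with r = 0.627, against 0.404 for spots 2 places apart, so that each feature has 2 neighbouring spots in each part of the list. The 532 spots with a symbol fell into 133 features of 4 spots with 1 symbol each, no spot had several, and 10220 had none. All 133 symbols occur in the RefSeq gene table, which is of strain 91-R6 and was used for names alone. It has no product descriptions, so the product patterns of the gene lists fixed before the data were examined could not be used, and lists were matched by symbol. Of 27 lists, 12 had no named member, 7 had 1 or 2, and 8 had at least 3 and were tested. Unnamed features are given by a number counted along the spot list.

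The direction of the ratios departs from the rule written before the data were examined. That rule took dye-swapped partners that correlate above 0 as already turned. Partners did correlate above 0 as deposited (r from 0.464 to 0.717), but the change from 0 mM to each dose correlated below 0 between the 2 orientations (r from -0.367 to -0.268). The ratio shared by all arrays had an SD of 0.208 across features. A per-feature dye offset of this kind could make partners correlate above 0 and leave the changes with dose below 0. The ratios were therefore read as Alexa 532 over Alexa 647 and the arrays with the mutant in Alexa 647 were turned, before any counts of genes were seen. The same rule called the direction likely only if both deleted genes were low in every sample. No feature used here is named sirR, so pyrF alone was checked, together with the order of words in the descriptions. By that rule the direction would not be called likely, and pyrF is weak evidence because of its high shared offset.

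The 4 spots of a feature were averaged, then the 2 arrays of a sample, which cancels an equal dye offset. The 8 samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per dose, no trend, not robust). There were 4 residual degrees of freedom and a prior of 8.17, and the median SE was 0.033 for a difference between doses and 0.023 against the reference. A call is a Benjamini-Hochberg adjusted p under 0.05 over 2688 features. The tests were the 0 and 1.5 mM means against 0, each dose against 0 mM, 1.5 against 0.8 mM, a moderated F test of any dose, and a slope per mM. Gene lists were tested with camera at a correlation of 0.01 with the named genes as background, with an estimated correlation and all features as alternatives.

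Genes were named by a rule fixed before the data were examined: pyrF always, the 10 highest and 10 lowest called named genes with the same sign in both sets (5 and 5 for the other comparisons), the 2 highest and 2 lowest unnamed features, and up to 4 members of each list by p. The list members are summarised by count. The figure of 22 genes, thiC among them, shows every named gene called at 1.5 mM. Additional lists (aminoacyl-tRNA synthetases, citrate cycle, histidine synthesis, histidine degradation, glutamate metabolism) were made after the values were seen.

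The fit was tested on simulated data with the observed noise, 2688 features and 200 changed ones. For 1.5 against 0 mM it recovered 30.8% of features changed by 0.1 log units and 99.4% of those changed by 0.2. For 0 mM against the reference it recovered 82.1% at 0.1. False calls were 4.1% to 8.2% of the calls. The control RNA had no spread in these sets. In 100 further sets without effect, added after the data were seen, the shared control was given the spread of a sample. Alternatives covered centring, scaling, spot summaries, single dye orientations, a dye term over 16 arrays, the set as a replicate block, each sample left out, variance models and fold thresholds. Figures were drawn with matplotlib 3.10.9.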

Results

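The series measured RNA levels in a strain of the halophilic archaeon Halobacterium salinarum NRC-1 that lacks ura3 and sirR. The gene ura3, listed in this annotation as pyrF, encodes orotidine-5'-phosphate decarboxylase of uracil synthesis, and its loss is the usual background for making deletions in this organism. The gene sirR encodes a metal-dependent transcriptional regulator. Cultures of the mutant with 0.0, 0.8, 1.0 or 1.5 mM MnSO4 were compared, as the title frames it, to follow the response to manganese. Each dose had 2 samples, called set A and set B, and each of the 8 samples was hybridised to 2 dye-swapped arrays against RNA of an NRC-1 control, giving 16 arrays. The time of exposure to manganese is not given in the sources used here. No label says that the sets came from separate cultures, so that p-values measure only the spread between these samples, which may be technical.

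Each array held 10752 spots, which the values grouped into 2688 features of 4 spots. Of these features 133 had a gene name and 2555 had none, so that the named genes were 4.95% of what was measured. The deposited values are log ratios whose base is not stated, and sizes are given in deposited log units, with the fold under base 10 and base 2 for a few of them. Array medians lay between 0.142 and 0.198. After turning to mutant over reference, sets A and B correlated across features with r between 0.815 at 1.5 mM and 0.927 at 1.0 mM; features are not independent replicates. The direction was taken as mutant over reference and is not certain. It rests on the wording of the sample descriptions and, weakly, on the deleted pyrF. Changes that mirror each other between the dye orientations argue against arrays turned before deposit, but only in features of low shared offset, where they do mirror. Such changes do not tell which way the ratio runs. Turned ratios could mirror too if a dye effect differed between the arrays with and without manganese. That cannot be excluded, because dose and the order of the arrays go together. If it runs the other way, every sign and every split of higher against lower given here is exchanged. If the ratios had instead been turned to mutant over reference before deposit, dpsA and argH would change in the opposite direction and by less. So would gdhA1, rpl12p, purF, lpdA and arcA, among others. If the ratios had been turned to reference over mutant, these genes would keep their direction but change by less. The deposited ratio of pyrF was positive in every array (0.037 to 0.649), so that last reading would also put the deleted gene low.

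The deleted gene was examined first. pyrF was lower in the mutant than in the reference in all 8 samples, with values from -0.289 to -0.068 and a mean of -0.179. At 0 mM the log ratio was -0.155 ± 0.030 (SE, n = 2; limma adjusted p = 0.00176), a fold of 1.43 under base 10 or 1.11 under base 2. This is a small deficit for a deleted gene, and whether its spots lie in the deleted part is not known. It rested on both dye orientations together: the arrays with the mutant in Alexa 532 alone gave 0.217 and those with the mutant in Alexa 647 alone -0.576. The ratio that pyrF shares over all arrays is high (0.396), in the range where changes did not mirror between orientations, and its own change with manganese went opposite ways in them (-0.093 and 0.029). pyrF is therefore weak evidence for the direction. The difference of pyrF between 1.5 and 0 mM did not pass (-0.088 ± 0.042, limma adjusted p = 0.194). The second deleted gene, sirR, and the transporter genes zurA, zurM and ycdH could not be reported because no feature used here carries their names.

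**Figure D1:**
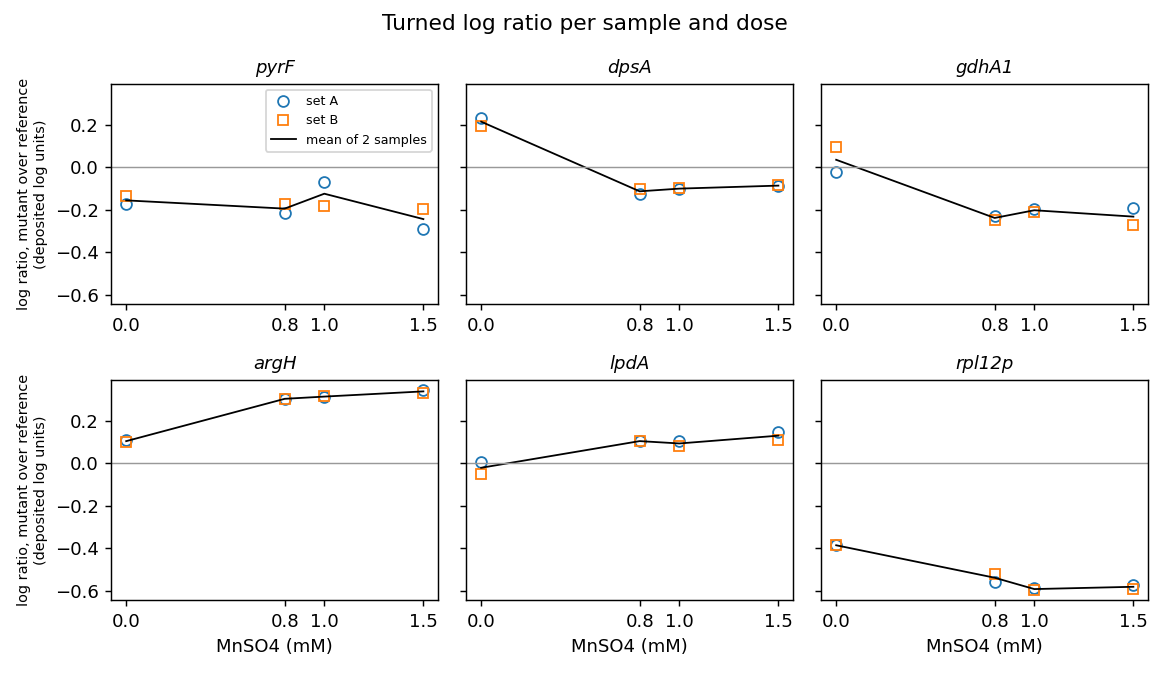
Log ratio of mutant over reference (vertical axis, deposited log units) against the MnSO4 concentration in mM for 6 named genes, with set A as circles, set B as squares and their mean as a line. dpsA went from 0.215 at 0 mM to -0.086 at 1.5 mM and argH from 0.105 to 0.339, while pyrF stayed below 0 in every sample.

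Without added manganese, the mutant had more RNA of dpsA, which encodes a ferritin-like iron storage protein, than the reference (0.215 ± 0.020, SE, n = 2; limma adjusted p = 6.76e-06). That is 1.64-fold under base 10 or 1.16-fold under base 2. The arginine deiminase gene arcA (0.186 ± 0.022) and the carbamate kinase gene arcC (0.128 ± 0.030), both of arginine fermentation, were higher as well, and so was the argininosuccinate lyase gene argH (0.105). The ribosomal protein genes rpl12p (-0.385 ± 0.021, limma adjusted p = 1.32e-07) and rpmC (-0.349 ± 0.021) were the lowest of the named genes. The fold of rpl12p is 2.43 under base 10 or 1.31 under base 2. In all, 9 named genes were higher and 34 lower than the reference, or 34 higher and 9 lower if the ratio runs the other way.

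Other genes higher in the mutant at 0 mM were the transducer genes htr6 (0.099) and htr1 (0.080), the glutamate dehydrogenase gene gdhB (0.080), the sensory rhodopsin gene sop1 (0.073) and moaC of molybdenum cofactor synthesis (0.063). Those lower by the most after the ribosomal genes were secY of the protein export channel (-0.264), the enolase gene eno (-0.207), the cytidylate kinase gene cmk (-0.196), sucD of succinyl-CoA synthetase (-0.177), cbiT of cobalamin synthesis (-0.171), the chaperone gene dnaK (-0.166), hemA of tetrapyrrole synthesis (-0.163) and the agmatinase gene speB (-0.157). All of these lay on the same side in both sets.

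By gene list, motility and chemotaxis had 11 named members. Of these 2 rose (htr1 and htr6), none fell and 9 did not pass the test, and adjusted over the list alone the count was also 2. The list stood above the other named genes (limma camera, adjusted p = 0.00126; adjusted p = 0.258 with an estimated correlation), and against all 2688 features its adjusted p was 0.10. With the ratios taken as already turned, motility and chemotaxis lay below the other named genes without passing (limma camera, adjusted p = 0.873). No list passed in a single dye orientation or with the first part of the spots. The other lists that were tested did not pass. Of 5 chaperone and proteolysis genes 2 were lower (dnaK and the proteasome gene psmB at -0.103). Matched by symbol, that list holds panB (0.062) and leaves out pan1 (-0.045). Which of these belongs in it is not known, and neither passed at 0 mM. Of 4 cobalamin genes 2 were lower (cbiT and cbiG at -0.087), and of 5 pyrimidine genes pyrF alone was lower. Of 4 replication genes gyrA was lower (-0.083), and of 4 bacteriorhodopsin and retinal genes sop1 was higher. None of the 7 purine genes and none of the 3 DNA repair genes passed. Among lists too small to test, both arginine fermentation genes were higher and both ribosomal protein genes and both respiratory chain genes (nuoL at -0.105 and sdhC at -0.089) were lower, as was phoU of phosphate uptake (-0.083), while the methionine sulfoxide reductase gene msrA did not pass (-0.036).

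Over all features, 685 differed from the reference at 0 mM, with 275 higher and 410 lower (limma, Benjamini-Hochberg). Among unnamed features the largest values were 0.803 ± 0.021 for feature 803 and 0.684 ± 0.028 for feature 2423, and the smallest were -0.703 ± 0.042 for feature 2217 and -0.471 ± 0.035 for feature 2581. The ratio leaves out the spread of the single control RNA, which alone would give 215 calls in simulated sets without effect if the control varied like a sample, and it cannot part the deletions from other differences between the cultures. Fitting only the 0 mM samples gave 1070 calls. Without set A at 0 mM the count was 320 and without set B 336, where the lone sample is assumed to vary like the others.

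In the samples with added manganese, dpsA was lower than at 0 mM, with the largest change of the named genes in either direction (0.029 if the ratios are taken as already turned). Dose and the order of the arrays go together, so that manganese is not shown to be the cause. At 1.5 mM against 0 mM the change was -0.301 ± 0.029 (SE, n = 2 per dose; limma adjusted p = 3.24e-05), 2.00-fold under base 10 or 1.23-fold under base 2. The glutamate dehydrogenase gene gdhA1 (-0.268 ± 0.040), rpl12p (-0.195 ± 0.029) and purF, which encodes the first enzyme of purine synthesis (-0.180 ± 0.035), were lower too. argH rose further (0.234 ± 0.028, limma adjusted p = 0.000241), 1.71-fold under base 10 or 1.18-fold under base 2. The dihydrolipoamide dehydrogenase gene lpdA (0.151 ± 0.031), the dCTP deaminase gene dcd (0.149 ± 0.033) and the chemotaxis response regulator gene cheY (0.140 ± 0.034) rose with it.

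**Figure D2:**
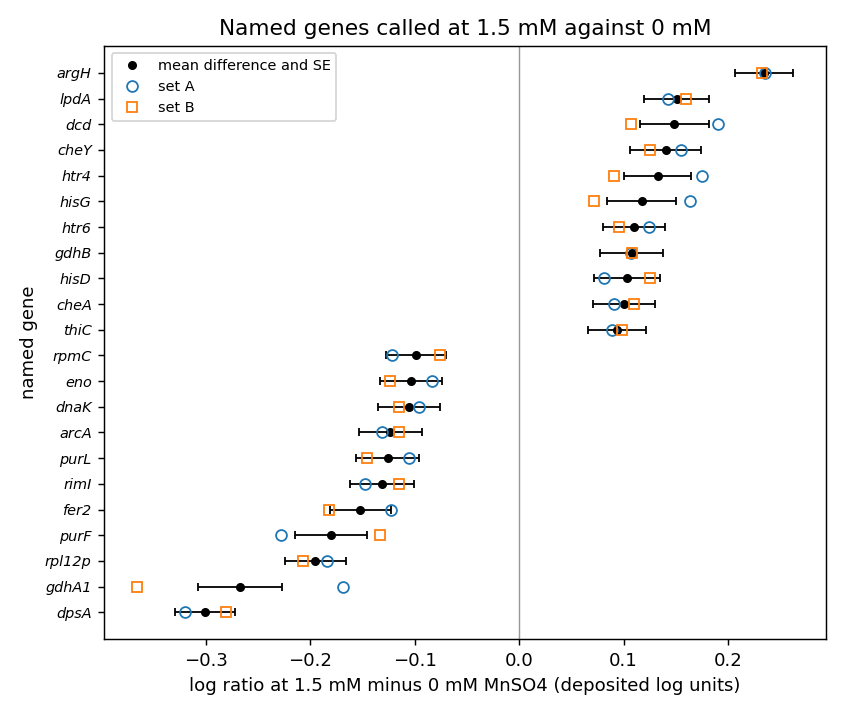
Change of the log ratio from 0 to 1.5 mM MnSO4 (horizontal axis, deposited log units) for the 22 named genes that passed the test, with the mean and its SE in black and the change within set A (circles) and set B (squares). The 11 genes that rose and the 11 that fell did so in both sets, and gdhA1 showed the widest gap between sets, -0.169 in set A and -0.366 in set B.

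Further genes higher at 1.5 mM than at 0 mM were htr4 (0.133), hisG and hisD of histidine synthesis (0.117 and 0.103), htr6 (0.110), gdhB (0.108) and the chemotaxis kinase gene cheA (0.10). Further genes lower were the ferredoxin gene fer2 (-0.152), rimI (-0.132), purL of purine synthesis (-0.126), arcA (-0.123), dnaK (-0.105), eno (-0.104) and rpmC (-0.099). gdhA1 and gdhB, both annotated as glutamate dehydrogenases, changed in opposite directions.

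Motility and chemotaxis genes stood above the other named genes at 1.5 mM against 0 mM (limma camera, adjusted p = 0.0315; adjusted p = 0.320 with an estimated correlation), with 4 of 11 higher (cheA, cheY, htr4 and htr6), none lower and 7 not passing. Adjusted over the list alone, 6 were higher. Purine synthesis genes stood below the others (adjusted p = 0.0315; adjusted p = 0.320 with an estimated correlation), with 2 of 7 lower (purF and purL), none higher and 5 not passing, and 3 lower adjusted over the list alone. Against all features purine synthesis passed (adjusted p = 0.0181) and motility and chemotaxis did not (adjusted p = 0.0718). With the ratios taken as already turned, purine synthesis stood above the others (adjusted p = 0.00887). Without the 1.5 mM sample of set A neither list passed. The other lists did not pass: of the chaperone genes dnaK alone was lower, and none of the 5 pyrimidine, 4 cobalamin, 4 replication, 3 DNA repair or 4 bacteriorhodopsin and retinal genes changed. Both ribosomal protein genes were lower. msrA, the one named gene of oxidative stress defence, did not pass (0.074 ± 0.030, limma adjusted p = 0.130), nor did phoU (-0.049), nuoL, sdhC or arcC (-0.074).

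In total 354 features differed between 1.5 and 0 mM. By the mean change over the manganese doses, 327 of them had the same direction in both dye orientations, against 58.9% of all features. A test on the average of the orientations itself favours such agreement. Of the 354 calls, 211 were higher and 143 lower. With each array centred on its median the split turned to 132 higher and 230 lower, and with arrays scaled to a common spread to 136 and 213, so that the share of rises against falls is not settled. The largest changes without a name were 0.638 ± 0.035 in feature 504 and 0.430 ± 0.031 in feature 1567 upward, and -0.807 ± 0.030 in feature 803 and -0.750 ± 0.029 in feature 2398 downward. Leaving out the 0 mM sample of set A or of set B left 97 or 104 calls, the arrays with the mutant in Alexa 532 alone gave 63, and fitting only the doses compared gave 208.

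At 0.8 mM against 0 mM dpsA (-0.328), gdhA1 (-0.274), fer2 (-0.194), sucD (-0.184) and rpl12p (-0.153) were lower (SE from 0.029 to 0.043), and argH (0.199), htr6 (0.131), lpdA (0.126), htr4 (0.119) and hisG (0.117) were higher. Of the features 109 were higher and 143 lower, or 150 and 128 after loess on the shared offset. dcd and cheY, higher at 1.5 mM, did not pass at 0.8 mM (limma adjusted p = 0.164 and 0.0913), and sucD did not pass at 1.5 mM (adjusted p = 0.0944). At 1.0 mM dpsA (-0.315), gdhA1 (-0.238), fer2 (-0.220), rpl12p (-0.206) and rimI (-0.194) were lower and argH (0.210), htr4 (0.156), dcd (0.147), gdhB (0.128) and htr1 (0.125) higher. Of 305 features called at 1.0 mM, 164 were lower, but after loess 174 were higher and 123 lower, so that the share of rises is not settled at these doses either. Purine genes stood below the other named genes at 1.0 mM (limma camera, adjusted p = 0.0362; adjusted p = 0.385 with an estimated correlation), with guaB (-0.176), purL (-0.176) and purF (-0.149) lower; at 0.8 mM the list did not pass (adjusted p = 0.0963). Without the 0 mM sample of set A or B the counts were 84 and 80 at 0.8 mM and 89 and 109 at 1.0 mM. Without the 0.8 mM sample of set A or B, 136 and 128 were called at 0.8 mM, and without the 1.0 mM sample of set A or B, 100 and 118 at 1.0 mM. Fitting only the doses compared gave 516 calls at 1.0 mM.

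The 3 dose comparisons share the 0 mM samples. Changes at 0.8 and 1.5 mM correlated across features with r = 0.837, against 0.500 in simulated sets without effect, and their covariance was 0.00543 against 0.000625. Of the calls at 0.8 and 1.5 mM, 99 features were higher in both, 99 were lower in both and none went opposite ways, where independent lists of these sizes would share 8.56 and 7.61. In all, 86 features were higher and 91 lower at every dose. Part of the overlap may come from the shared 0 mM samples. With set A of one dose set against set B of the other, so that no sample was shared, r was 0.602 and 0.667. An error common to both 0 mM samples would remain in these values.

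Any manganese dose against 0 mM was tested with a moderated F test. It called 17 named genes: argH, lpdA, dcd, htr4 and htr6 higher and dpsA, gdhA1, rpl12p, purF, fer2, rimI, purL, arcA, sucD, speB, carB and guaB lower, by their change at 1.5 mM. Of these dpsA had an adjusted p of 2.95e-05 and argH of 0.00065. Over all features 260 passed, 231 of them with the same direction in both dye orientations. Of the 260, 115 were higher and 145 lower, or 94 and 197 with each array centred on its median and 153 and 119 after loess. The count fell to 45 without set A at 0 mM and to 40 without set B, was 144 and 158 without set A or B at 1.0 mM, and rose to 401 without set A at 1.5 mM.

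The highest and the lowest added dose could not be told apart. Between 1.5 and 0.8 mM no named gene and no feature passed (limma, smallest adjusted p = 0.174), while 248 features had an unadjusted p under 0.05 where chance gives 134.4. For dpsA the difference was 0.027 ± 0.029. With the set letter as a replicate block 5 features passed, though the letters do not pair the samples. Without set A at 1.5 mM 9 features passed, without set B at 0.8 mM 2 did, with median centring 4, with scaling 5 and with the first part of the spots 1. In simulated data for this comparison, 98.9% of 200 features changed by 0.2 log units were recovered and 27.6% of those changed by 0.1. The linear trend over dose called 172 features higher and 115 lower, or 110 and 184 with median centring. The slope was 0.163 per mM for argH and -0.214 per mM for dpsA, with both signs exchanged if the ratio runs the other way. A slope cannot tell a graded response from a step between 0 mM and any added dose. At 0, 0.8 and 1.5 mM dpsA lay at 0.215, -0.113 and -0.086, and argH at 0.105, 0.304 and 0.339. Without set A or B at 0 mM the trend count fell to 45 or 32.

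At 1.5 mM the mutant was compared with the reference again. The named genes furthest above it were argH (0.339 ± 0.020), htr6 (0.209 ± 0.021), cheY (0.199 ± 0.024), gdhB (0.187 ± 0.022) and htr1 (0.172 ± 0.022), and those furthest below were rpl12p (-0.581 ± 0.021), rpmC (-0.448 ± 0.021), eno (-0.311 ± 0.021), sucD (-0.294 ± 0.030) and dnaK (-0.271 ± 0.021). Of the 11 motility and chemotaxis genes 7 were higher and none lower (limma camera, adjusted p = 0.000264; adjusted p = 0.189 with an estimated correlation). All 4 cobalamin genes were lower and 3 of 4 bacteriorhodopsin and retinal genes higher, though neither list passed (adjusted p = 0.125 and 0.0981). dpsA, above the reference at 0 mM, was below it at 1.5 mM (-0.086 ± 0.020, limma adjusted p = 0.00486).

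Over all features 582 were higher and 487 lower than the reference at 1.5 mM, or 442 and 573 with arrays scaled to a common spread. Fitting only the 1.5 mM samples gave 619 calls. Of the features called at both 0 and 1.5 mM, 182 were higher and 294 lower at both and 30 went opposite ways. Independent lists would share 59.5 and 74.3. Both comparisons use the same control RNA, and in simulated sets without effect, with a control that varied like a sample, 38.4 were higher and 38.5 lower at both, and at most 57 and 63. The covariance of the ratios at 0 and 1.5 mM was 0.00652, where the highest of those sets reached 0.00136. Their correlation across features was r = 0.668, against 0.666 in those sets, so r by itself shows no excess over a shared control. A control that varied more than a sample, or a dye offset unequal between the orientations, is not covered by these sets.

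The change with manganese mirrored between the dye orientations in features of low shared offset and not in those of high offset. Features were divided into 6 classes of 448 by the ratio they share over all arrays. Of the calls for any dose, 100%, 98.4% and 92.3% had the same direction in both orientations in classes 1, 2 and 3. In classes 4, 5 and 6 the shares were 71.4%, 50% and 57.9%, so that many calls of high offset did not hold in both.

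**Figure D3:**
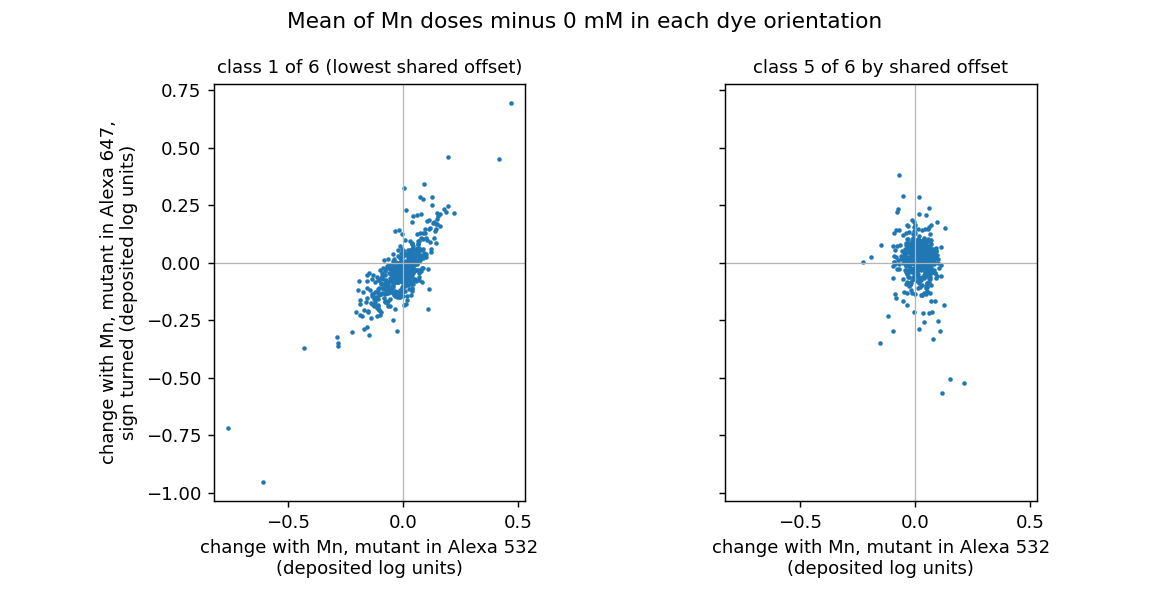
Change of the ratio from 0 mM to manganese with the mutant in Alexa 647, turned (vertical axis), against the change with the mutant in Alexa 532 (horizontal axis), both in deposited log units, for class 1 and class 5 of shared offset. As deposited, r corrected for noise was -0.857 in class 1 and 0.411 in class 5, so that after turning the orientations rise together in class 1 and not in class 5.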

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

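Of the tests below, only the count over other splits of the samples was set before its result was seen; the others were chosen after. Among 24 groups (6 summary values in the 4 arrays of each of 4 doses), 3 had an array far from the other 3, where chance gives 1.2. The array of 1.0 mM set B with the mutant in Alexa 647 had a highest spot value of 2.82, the next being 1.22. The array of 0.8 mM set A with the mutant in Alexa 532 had a highest spot value of 0.937, the nearest being 1.16. The array of 1.0 mM set A with the mutant in Alexa 647 had 24 spots at exactly 0, the next having 2. dpsA was above the reference at 0 mM and below it at 1.5 mM, and the difference itself passed the test (-0.301). It was the one named gene of 30 features called in opposite directions at these doses with a called change between them.

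Dye-swapped partners correlated above 0 as deposited, the first pattern weighed. Ratios turned before deposit would make the changes with manganese correlate above 0 between orientations if dye effects were alike at all doses. Over all features the highest of the 3 values was -0.268, which argues against that reading. In features of high shared offset it is not argued against. There r of the change with manganese, corrected for noise, was 0.231 in the upper part by shared offset, against -0.696 in the lower part. A dye effect that differed between the arrays with and without manganese could also give values below 0 and was not tested. A dye offset of each feature shared by all arrays requires partners to correlate below 0 once the mean of the arrays of the other doses is subtracted. All 8 pairs did, the highest at -0.409. Ratios turned before deposit that kept a dye effect would give this as well, so the test cannot tell these readings apart. No biological explanation was tested.

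The change with manganese was larger in the arrays with the mutant in Alexa 647, with a reproducible SD 2.01 times (1.85 to 2.19 over resampled features) that of the other orientation. It mirrored the other orientation only in part. RNA of cells given FeSO4 in place of manganese on all swapped arrays, which is 1 reading of their growth text, would leave no mirrored change. In the class of 448 features with the lowest shared offset, r between orientations corrected for noise was -0.857 (-0.900 to -0.798), which argues against that reading. FeSO4 given together with manganese could leave a mirrored change, so this test cannot decide on it. In the classes above it, r was -0.712, -0.397, 0.093 and 0.411, and in the highest class no reproducible change was left in Alexa 532. The upper part of the features by shared offset had r higher than the lower part by 0.927 (0.694 to 1.14). The intervals in this paragraph are over resampled features and leave out the spread between samples. That features of high offset do not follow the RNA stays open: mirroring is lost, but with the mutant in Alexa 647 the reproducible SD was still 0.116 and 0.090 in classes 4 and 5, against 0.128 in class 1. In class 6, of the highest offset, that SD was 0.034. No biological explanation was tested.

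Most of the change was shared by all manganese doses and set the 0 mM samples apart. Of 28 splits of the 8 samples into 2 and 6, 1 gave as many calls as 0 mM against manganese: the real one with 402, the highest other giving 0. This argues against chance as far as 28 splits can. Every other split has a 0 mM sample among the 6, which widens the spread, so the counts of 0 partly follow from the same change. The covariance between the changes at 0.8 and 1.5 mM was 0.00543, where the highest of 100 simulated sets without effect reached 0.000714. This argues against the shared 0 mM samples alone if their error is no more than the spread between sets A and B. An error common to both 0 mM samples is not covered by these sets. After a loess correction of the turned ratios along the shared offset, 309 of the 354 calls at 1.5 mM stayed. This argues against a smooth dye curve left after turning as the source of most calls. Dye effects that differ between features of like offset would pass the correction, so it cannot decide on them. A batch acting on the dyes alike in both orientations is argued against as the sole cause by r = -0.499 over all features. The interval of this r over resampled features (-0.590 to -0.404) leaves out the spread between samples. Such a batch is not argued against in features of high offset, where r was 0.093 in class 4 and 0.411 in class 5. A batch of cultures or RNA that follows the dose cannot be told apart from manganese, because arrays were numbered dose by dose and 0 pairs of doses overlap in number. A response to manganese stays open beside it.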

How the results depend on the processing

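The alternatives "already turned", exact zeros as missing, loess on the shared offset, parts of the spot list, features of low offset and camera against all features were chosen after seeing the data. The cause of a change was not tested unless stated. Median centring, scaling, the median of the 4 spots, the dye term over 16 arrays, the trended robust variance, exact zeros as missing, loess and a filter that left out 15 features kept every total count within 1.5 times the main one, except that centring gave 4 and scaling 5 calls between 1.5 and 0.8 mM, and scaling left 1 list, purine synthesis, at 1.5 mM against 0 mM. The splits moved more: centring turned 211 higher and 143 lower at 1.5 mM to 132 and 230, and 172 and 115 for the trend to 110 and 184. Loess moved the split of any dose to 153 higher and 119 lower, of 0.8 mM to 150 and 128 and of 1.0 mM to 174 and 123.

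A single orientation cannot cancel the dye offset, which by construction fills the comparisons with the reference. With the mutant in Alexa 532 alone there were 2123 calls at 0 mM and 2251 at 1.5 mM against the reference, 40 for any dose, 29, 36 and 63 at 0.8, 1.0 and 1.5 mM against 0 mM, and 67 for the trend. Sets A and B correlated with a mean r of 0.957, 0 lists passed at 0 mM and 1 at 1.5 mM against 0 mM. The mean of pyrF reversed to 0.217, and at 0 mM arcA (-0.016), argH (-0.063), gdhB (-0.186), pyrF (0.287) and gyrA (0.0065) reversed, as did gdhB against the reference at 1.5 mM (-0.129). With the mutant in Alexa 647 alone there were 2066 and 2085 calls against the reference, pyrF lay at -0.576, r was 0.933, and 0 and 1 lists passed. At 0 mM eno (0.038), nuoL (0.145), sdhC (0.103), psmB (0.065) and cbiG (0.069) reversed.

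Taking the ratios as already turned, the rule as written before the data were examined, gave 2188 and 2225 calls against the reference at 0 and 1.5 mM, 46 for any dose, 52, 46 and 66 at 0.8, 1.0 and 1.5 mM, and 66 for the trend, with r at 0.964 and with 0 and 1 lists. The directions of the named genes rest on this choice. pyrF reversed to a mean of 0.396. At 0 mM dpsA (-0.197), arcA (-0.202), argH (-0.168), gdhB (-0.265), moaC (-0.029), feature 803 (-0.209), feature 2423 (-0.036), rpmC (0.096), cbiT (0.060), speB (0.015), feature 2217 (0.218), feature 2581 (0.310), pyrF (0.442), phoU (0.033) and gyrA (0.090) reversed, and so did motility and chemotaxis (limma camera, adjusted p = 0.873). At 1.5 mM against 0 mM, and for any dose where called, argH (-0.141), lpdA (-0.011), dcd (-0.047), htr4 (-0.0065), hisG (-0.027), htr6 (-0.068), gdhB (-0.051), feature 504 (-0.129), feature 1567 (-0.029), dpsA (0.029), gdhA1 (0.00059), rpl12p (0.025), purF (0.110), rimI (0.087), purL (0.068), arcA (0.115), eno (0.046) and feature 803 (0.163) reversed. So did sucD (0.013), carB (0.052) and guaB (0.057) for any dose and purine synthesis (limma camera, adjusted p = 0.00887).

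At 0.8 mM the same reading reversed argH (-0.147), htr6 (-0.085), lpdA (-0.032), htr4 (-0.097), hisG (-0.027), dpsA (0.025), gdhA1 (0.045) and fer2 (0.013). At 1.0 mM it reversed argH (-0.090), dcd (-0.070), gdhB (-0.0042), htr1 (-0.033), dpsA (0.044), gdhA1 (0.024), fer2 (0.054), rpl12p (0.078) and rimI (0.034). Against the reference at 1.5 mM it reversed argH (-0.309), htr6 (-0.044), cheY (-0.109), gdhB (-0.316), htr1 (-0.0019) and rpmC (0.061). No other alternative reversed a named gene.

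Leaving out 1 sample at a time, calls ranged from 320 to 807 at 0 mM against the reference, from 40 to 401 for any dose, from 80 to 363 at 0.8 mM, from 89 to 416 at 1.0 mM, from 97 to 385 at 1.5 mM, from 0 to 9 between 1.5 and 0.8 mM, and from 32 to 342 for the trend. Lists at 1.5 mM against 0 mM ranged from 0 to 2. Fitting only the samples compared, with fewer degrees of freedom, gave 1070 and 619 calls against the reference at 0 and 1.5 mM, 516 at 1.0 mM and 208 at 1.5 mM.

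Spots of the first part of the list alone gave 173 calls for any dose, 165 at 1.0 mM, 196 at 1.5 mM, 1 between 1.5 and 0.8 mM, 161 for the trend and 0 lists at 0 mM. The second part gave 395 calls at 0 mM, 57 for any dose, 76, 71 and 85 at the 3 doses, 72 for the trend, r of 0.772 and 0 lists at 1.5 mM. The features of lower shared offset alone, fewer being tested, gave 397 for any dose, r of 0.948 and 1 list at 1.5 mM. The rank of dose gave 89 for the trend.

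The set letter does not pair the samples, since the difference of set A and B correlated between doses with r from -0.079 to 0.113 over 6 pairs. As a replicate block it gave 337 calls at 1.5 mM against 0 mM and 5 between 1.5 and 0.8 mM, and moved no other count by over 1.5 times.

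Changes of at least 2-fold under base 10 numbered 39 and 73 against the reference at 0 and 1.5 mM, 22 for any dose, 20, 20 and 22 at 0.8, 1.0 and 1.5 mM. Under base 2 there were 0 in each. An estimated correlation left 0 and 0 lists, fry called 5 at 0 mM, and camera against all features 0 and 1 (purine synthesis). A rule for 1 of 2 arrays missing was not run, no value being missing. The dye term was not run for lists, and the fold threshold not for lists or the trend. Spot intensities were not used here, so what signal over background limits is unknown.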

Other observations

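The lists in this paragraph were made after the values were seen, and their tests are over 5 lists. Of 6 citrate cycle genes, 5 were lower than the reference at 0 mM and 5 at 1.5 mM: sucD (-0.177 and -0.294), sucC (-0.116 and -0.222), mdh (-0.097 and -0.169), icd (-0.083 and -0.115) and sdhC (-0.089 and -0.111), while the citrate synthase gene citZ was not called (0.009 and -0.038). Against the other named genes the list did not pass at 0 mM (limma camera, adjusted p = 0.232) and passed at 1.5 mM (adjusted p = 0.0477; adjusted p = 0.593 with an estimated correlation). Between 1.5 and 0 mM none of its members passed. Of 12 aminoacyl-tRNA synthetase genes lysS alone passed against the reference at 0 mM (-0.132), and none passed between 0 and 1.5 mM. Of 6 histidine synthesis genes hisG and hisD rose at 1.5 mM against 0 mM and 4 did not pass; the 3 histidine degradation genes did not pass. Of 4 genes of glutamate and glutamine metabolism gdhB rose, gdhA1 fell, and gdhA2 (-0.023) and the glutamine synthetase gene glnA (-0.024) did not pass.

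Genes of arginine metabolism, chosen after their values were seen, went different ways with manganese. arcA went from 0.186 at 0 mM to 0.063 at 1.5 mM, arcC went from 0.128 to 0.054 without passing (adjusted p = 0.289), and argH rose from 0.105 to 0.339. speB lay at -0.157 and -0.242.

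Some features changed with manganese in the ratio as deposited, averaged over both orientations without turning. With unturned ratios 46 features passed for any dose, 25 of which also passed after turning. The strongest was feature 2352, whose deposited ratio rose by 0.211 with the mutant in Alexa 532 and by 0.521 with the mutant in Alexa 647.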
